A study of Mus musculus with 3 samples.

How the data were processed

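Droplet single-cell RNA sequencing was done on 3 libraries of sorted lung myeloid cells, all in the B16F10 lung metastasis group (B16F10 is a mouse melanoma line given intravenously), each from 3 pooled lungs of mice at day 16. About 30000 cells were loaded per library, with about 50000 reads per cell, per the labels. Replicates 1 and 2 hold 31816 and 35591 barcodes, more than that number, and the reason is not known. The deposited matrices hold raw UMI counts per gene and barcode, which the authors made with Cell Ranger on the mouse genome GRCm38. The matrix headers name Cell Ranger 8.0.0 while the submitters' notes name Cell Ranger 6.1, R 4.2 and Seurat 4.3, and which version made the counts is not known. The other deposited files hold identifiers of barcodes and genes (unit: other) and no measurement. Barcodes in the matrices had been called as cells by the authors, and the lowest UMI number per barcode differed between the libraries. Libraries held 376186954 to 644354779 UMIs over all barcodes. A share of cells in a single library is given with an exact 95% binomial interval, and a share of 0 is taken as 3 cells where it enters a ratio, per library.

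Barcodes with at least 500 genes and under 10% mitochondrial counts were kept (1807, 1754 and 18 removed), and doublets were called in each library with scrublet within scanpy 1.11.5 (3760, 4489 and 1033 removed). Counts were scaled per cell and log-transformed, and 2000 variable genes were chosen across libraries. Mitochondrial, ribosomal, haemoglobin and immunoglobulin genes, Gm42418, Gm26917, Malat1, Xist, AY036118, Cmss1 and every gene of the tested lists were kept out of them. Genes were scaled within each library, 30 principal components and 15 neighbours were used, and cells were clustered with Leiden at resolution 1 (leidenalg 0.10.2, igraph 0.11.9) into 31 clusters. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

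Clusters were named from 20 marker lists, with "-like" added since no other evidence of identity was used. A cluster's score for a list was the mean over its genes of the log2 ratio, with 10 CPM added, of the cluster to the other clusters, limited to between -3 and 3. The best list had to score at least 0.5, at least 0.5 times the highest score any cluster had for that list, and at least 0.15 above the next list (a C1q name was kept over a close Lyve1 score), with at least 3 markers seen in 10% of the cells. A cluster was left unnamed where its top 10 genes held more markers of another list, where it was shallow with no own marker among them, or where immunoglobulin genes led it. This rule was set after the clusters were seen, cluster 11 included, and before any test, and it left cluster 11 unnamed. The 12 named classes and 8 unnamed clusters include 2 named classes and 2 clusters with under 50 cells in a library, which were not tested.

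Counts were summed per library and class, and 16 classes with at least 50 kept cells in every library entered 1 fit of 48 profiles and 16080 genes. The edgeR 4.0.16 quasi-likelihood test (R 4.3.3, filterByExpr, TMM, robust dispersions) had the library as a block, since the classes compared come from the same libraries. Profiles of the same library deviated from their class means together, with r across genes of 0.317 to 0.663, against -0.563 to 0.244 for profiles of different libraries. Genes are not independent replicates, and these r values describe the profiles only. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and numbers of changed genes are over the 14310 genes not used to cluster. Comparisons were C1q macrophage-like against classical monocyte-like, alveolar macrophage-like against C1q macrophage-like and Trem2 lipid-associated macrophage-like against C1q macrophage-like cells, with each class against the mean of the others for the M1 and M2 panels. A fit of 24 single clusters (16286 genes) gave cluster 11 against cluster 17, a comparison added after the clusters were seen.

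The 12 tested lists were the M1 and M2 panels, interferon response, MHC class II, MHC class I, glycolysis and hypoxia, immune regulation, chemokines, uptake receptors, lysosome and proteases, immediate early and stress, and cell cycle genes, with 210 genes of which Cxcl11, Mx1 and Clec7a were not found under those names. Some genes are in more than 1 list. Lists were tested with camera of limma 3.58.1 at its preset correlation, with an estimated correlation beside it, against genes not used to cluster (fry was also run, and its values are not reported here). Genes are named by this rule for each comparison: up to 5 of each panel and up to 2 of each other list with the largest absolute log2 fold change among members that passed, moved the same way in 3 of 3 libraries and reached 20 CPM in the higher class, and the 4 most raised and 4 most lowered genes outside the lists and outside the clustering genes. Arg1, Nos2, Mrc1, Il1b, Cxcl9, Cd274, H2-Ab1, Fcgr1, Itgam and Ptprc are always named. A few genes that the rule picks are not reported here. Nos2 was too low for the fold changes, so its levels are given. Coordinates came from the GENCODE annotation of GRCm38, which matched 108 of 108 genes named by the rule. CPM values are summed raw counts scaled to equal totals.

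For correlations, co-detection and cycling, each cell was thinned to 2000 UMIs without replacement (508, 606 and 0 shallower cells left out). Panel members with a UMI in at least 2% of the thinned cells entered the mean Pearson correlation over gene pairs, compared with 1000 random list pairs drawn from the 100 genes nearest in level to each member. Co-detection of 8 gene pairs fixed in advance was the number of cells with both genes over the number if independent, given where at least 5 cells were due if independent. Cycling cells had a UMI of at least 2 of 10 cell cycle genes.

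The tests were tried on simulated data. With 100 genes changed 2-fold in summed counts, edgeR recovered 80%, 77% and 71% in the 3 comparisons in the order above, and 23%, 32% and 22% of those changed 1.5-fold, with 4, 10 and 10 of 15880 unchanged genes called. A planted list was called by camera in each and 0 of 20 random lists were. For correlations, independent simulated genes fell at percentiles 4.3, 93.2 and 90.3 of random lists (within M1, within M2 and between). Modules planted independently of each other gave 0.366 and 0.256 within and 0.00890 between, all at percentile 100. Alternatives tried were RLE in place of TMM, the Wald test of DESeq2 1.42.0, no filter on low counts, no replicate block, only the 2 classes in the fit, each replicate left out, thinned cells, doublets kept, a stricter cell filter (1000 genes, 5% mitochondrial counts), tested lists among the clustering genes, resolutions 0.5 and 1.5, scaling over all cells and other thinning depths (1000 and 4000 UMIs). Chosen after the data were seen were the UMI minimum of replicate 3 in every library, cluster 11 counted as classical monocyte-like, cycling cluster 9 left out, all alternatives for cluster 11 against cluster 17, and leave-one-out for panel levels and for markers outside the sort gate. Raw reads were not used here.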

Results

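Myeloid cells from tumour-bearing lungs of C57BL/6 mice were profiled by droplet single-cell RNA sequencing (10x Genomics 3′ chemistry). The mice had received 400000 B16F10 cells, a mouse melanoma line that seeds the lung, by intravenous injection and were studied on day 16. An intravenous antibody to CD45 given 5 minutes before harvest marked cells inside vessels, and extravascular cells positive for CD64 (Fcgr1), the high-affinity Fc gamma receptor of macrophages and monocytes, and for CD11b (Itgam), an integrin of myeloid cells, were sorted. There was 1 group with 3 libraries, each a pool of 3 lungs, named replicates 1 to 3 here. Whether the pools came from different animals is not known, so n = 3 counts pools. Replicates 1 and 2 formed 1 batch and replicate 3 a second, so batch and replicate 3 cannot be told apart. The title of the series concerns M1 and M2 myeloid cells, so the comparisons were made between cell classes found in the same libraries, and the genes of an M1 and an M2 panel fixed before the data were examined were followed through them.

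The libraries held 31816, 35591 and 18052 barcodes with 546456016, 644354779 and 376186954 unique molecular identifiers (UMIs). Median UMIs per barcode were 14537.5, 15631 and 18391. The lowest barcode had 500 UMIs in replicate 1, 500 in replicate 2 and 5704 in replicate 3. After filters on genes, mitochondrial counts and doublets, 26249, 29348 and 17001 cells stayed (72598 in all). Intervals on shares of cells are exact (Clopper-Pearson) 95% intervals and cover counting error only. The edgeR p-values set a class difference against how it varied over these 3 pools, with the library as a block. Their dispersion was estimated over all classes in the fit. The camera p-values compare the genes of a list with other genes. None of them covers spread beyond these 3 pools.

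The largest class was C1q macrophage-like cells, marked by the complement genes C1qa, C1qb and C1qc, with 27.4% ± 6.61 (SD, n = 3) of the kept cells. Lyve1 resident macrophage-like cells made up 15.2% ± 4.19, conventional dendritic cell type 2-like (cDC2) cells 14.0% ± 1.47, alveolar macrophage-like cells 10.7% ± 1.43 and classical monocyte-like cells 5.63% ± 0.243. Trem2 lipid-associated macrophage-like cells (Trem2 cells), with the lipid and tissue-remodelling genes Trem2, Gpnmb and Spp1 among their markers, were 4.98% ± 5.83. Smaller classes were conventional dendritic cell type 1-like (cDC1) cells with 4.76% ± 3.95, nonclassical monocyte-like cells with 0.965% ± 0.190, neutrophil-like cells with 0.951% ± 0.325 and migratory dendritic cell-like cells with 0.730% ± 0.289. Several classes had few transcripts of a sort gene, with Itgam lowest of the 16 tested classes in alveolar macrophage-like cells and Fcgr1 low in cDC1 and cDC2 cells, and how they passed the gate was not tested. Clusters without a name and large enough for the comparisons were cluster 11 (5.43% ± 7.83), cluster 7 (4.35% ± 0.967), cluster 13 (1.84% ± 0.836), cluster 1 (1.46% ± 0.467), cluster 8 (0.828% ± 0.382) and cluster 28 (0.402% ± 0.0723). Cluster 11 was nearest to the classical monocyte list, cluster 28 scored within the naming margin for both the fibroblast and melanoma lists, and immunoglobulin genes led cluster 8. Median depths in replicates 1, 2 and 3 were 11197, 12650 and 13261.5 UMIs in C1q cells, 13123.5, 14602 and 16750 in classical monocyte-like cells, 28410, 30981 and 25182 in alveolar macrophage-like cells, 17051.5, 19621.5 and 30192 in Trem2 cells and 14909.5, 15833 and 18615 in cluster 11.

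Trem2 cells and cluster 11 were unevenly spread over the libraries. Trem2 cells were 1.58% (1.43 to 1.74%), 1.65% (1.51 to 1.80%) and 11.7% (11.2 to 12.2%) of replicates 1, 2 and 3. Cluster 11 was 0.891% (0.781 to 1.01%), 0.923% (0.817 to 1.04%) and 14.5% (13.9 to 15%). In contrast, cDC1 cells were 8.68%, 4.82% and 0.776%, and C1q cells 31.9%, 30.4% and 19.8%. Alveolar macrophage-like cells came mostly from cluster 14 in replicates 1 and 2 and from cluster 15 in replicate 3. Batch 1 holds 2 libraries and batch 2 only 1, so no test between batches was made. Shares of several classes depended on the processing. Lyve1 cells were 5.39% with cells called as doublets kept, 5.95% with the stricter cell filter and 5.53% with the tested lists among the clustering genes. They were 8.08% with genes scaled over all cells and 21.2% at resolution 0.5, where Trem2 cells were 10.5%. With genes scaled over all cells, C1q cells were 9.67% and classical monocyte-like cells 11.8%. With the UMI minimum of replicate 3 in every library, neutrophil-like cells were 0.545%. Cluster 7 was 2.68% with doublets kept, cluster 1 was 2.48% at resolution 1.5 and cluster 28 was 0.652% at resolution 0.5. No class matched cluster 11 at resolution 0.5, where 94.3% of its cells were in the Trem2 class, or with genes scaled over all cells, where 87.6% were in the classical monocyte-like class. In replicate 3 these classes were then 25.9% and 21% of the cells. The 12 named classes together held 85.6% ± 7.38 of the cells.

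**Figure D1:**
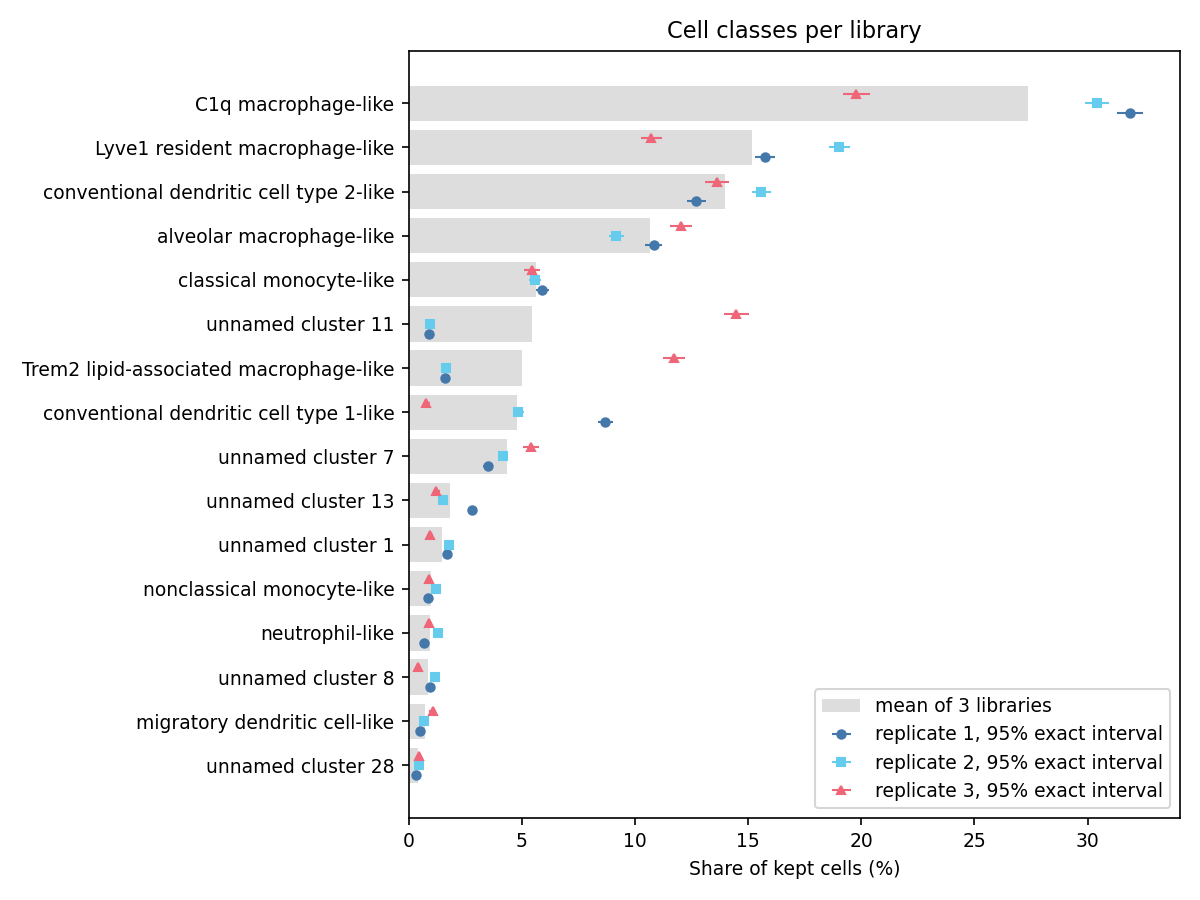
Share of kept cells in each class (percent) for the 3 libraries, with points and exact 95% intervals for replicates and bars for the mean. Trem2 cells and cluster 11 are highest in replicate 3, at 11.7% and 14.5%.

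Arg1, the arginase gene used as an M2 marker, was highest in cluster 11 at 63.3 ± 85.6 CPM (summed counts scaled to equal totals, SD, n = 3) and next in Trem2 cells at 37.7 ± 56.9. Replicate 3 carried most of it: cluster 11 had 10.5, 17.2 and 162 CPM and Trem2 cells 8.48, 1.35 and 103 in replicates 1, 2 and 3. By replicate, Arg1 was 0.565, 0.487 and 17.3 CPM in C1q cells and 0.189, 0.365 and 1.10 in alveolar macrophage-like cells. Nos2, the inducible nitric oxide synthase that marks M1 cells, was 1.39, 0.689 and 2.61 CPM in cluster 11 by replicate. A Nos2 UMI was found in 39 of 2966 cluster 11 cells, 10 of 20658 C1q cells and 5 of 7576 alveolar macrophage-like cells, all unthinned. The chemokine gene Cxcl9 reached 735 ± 299 CPM in cluster 11, against 105 ± 84.9 in migratory dendritic cell-like cells (37.0, 78.1 and 200.3 by replicate) and 19.6 ± 2.46 in C1q cells. Il1b, the gene of an inflammatory cytokine, was 11477 ± 3402 CPM in neutrophil-like cells, 1326 ± 172 in cluster 11 and 62.3 ± 30 in Lyve1 cells.

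Mrc1, the mannose receptor CD206, was 4090.5 ± 362 CPM in Lyve1 cells, 2105 ± 409.9 in alveolar macrophage-like cells and 38.0 ± 9.78 in classical monocyte-like cells. Cd274, which encodes the checkpoint ligand PD-L1, was highest in migratory dendritic cell-like cells at 413 ± 145 CPM and reached 137 ± 12.2 in alveolar macrophage-like cells, 128 ± 42.3 in cluster 11 and 15.1 ± 4.24 in C1q cells. H2-Ab1, an MHC class II chain, was 9311 ± 977 CPM in cDC2, 4997 ± 1421 in C1q and 270.0 ± 61.1 in classical monocyte-like cells. Fcgr1, one of the sort genes, was 254 ± 114 CPM in cluster 11, 188 ± 80.2 in Lyve1 cells, 15.9 ± 21.1 in cDC1 and 25.6 ± 25.6 in cDC2 cells. Fcgr1 was highest in replicate 3 in every tested class but alveolar macrophage-like cells. It was 3.01, 4.32 and 40.2 CPM in cDC1 and 9.64, 11.9 and 55.1 in cDC2 cells of replicates 1, 2 and 3. In C1q cells it was 108, 93.2 and 233 CPM in that order. Itgam was 551 ± 79.8 CPM in neutrophil-like cells and 6.57 ± 1.18 in alveolar macrophage-like cells. Ptprc, which encodes CD45, was 1839 ± 95.7 CPM in classical monocyte-like cells and 742 ± 57.6 in C1q cells.

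The genes followed in most detail are protein coding and lie, on the mouse genome GRCm38, as follows. Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484, minus strand), Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079, minus strand) and Mrc1 (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057, plus strand) come first. Cd274 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095, plus strand), H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419, plus strand) and Chil3 (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564, minus strand) follow. The others are Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981, plus strand), Vegfa (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369, minus strand), Ctsd (ENSMUSG00000007891, chromosome 7, 142375911 to 142388038, minus strand) and C1qc (ENSMUSG00000036896, chromosome 4, 136889804 to 136893065, minus strand).

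Genes of both panels were raised in each of the 16 classes tested: every class had at least 1 M1 member and at least 1 M2 member above the mean of the other classes. In the pairwise comparisons below, 8526, 8431 and 4731 of 14310 genes changed, so calls were frequent among all genes. The share of all genes raised in the contrasts used here is not given. At least 1 raised member per panel was therefore not shown to be particular to these panels. Cluster 11 had 17 raised M1 members and 13 raised and 2 lowered M2 members (14 and 2 adjusted over the list alone). It was raised, on the log2 scale, for the M1 genes Cxcl9 (5.90 ± 0.21), Ccl5 (3.50 ± 0.36) and Il12b (2.67 ± 0.43), which encode chemokines and a subunit of interleukin 12, and for the M2 genes Arg1 (5.25 ± 0.30) and Ccl24 (3.72 ± 0.28). The scavenger receptor gene Cd163 (-3.02 ± 0.46) and Mrc1 (-1.05 ± 0.23) were lowered there. Migratory dendritic cell-like cells had 14 raised M1 members and 6 raised and 7 lowered M2 members (6 and 8 adjusted over the list alone), among them Il12b (9.60 ± 0.25) and the chemokine gene Ccl22 (8.56 ± 0.15). Cluster 7 had 12 raised and 4 lowered M1 members (13 and 4 adjusted over the list alone) and 17 raised and 3 lowered M2 members (17 and 4 adjusted over the list alone). Without replicate 1, the raised and lowered counts were 11 and 2 M1 members in cluster 7. Without replicate 2, the raised and lowered counts were 11 and 1 M1 members in cluster 7 and 15 and 1 M2 members in cluster 7. With no replicate block, the raised and lowered counts were 10 and 1 M1 members in cluster 7.

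Alveolar macrophage-like cells had 2 raised and 17 lowered M1 members and 9 raised and 13 lowered M2 members (9 and 14 adjusted over the list alone): the chitinase-like gene Chil3 (6.46 ± 0.21) and the formyl peptide receptor gene Fpr2 (5.24 ± 0.16) were raised and the costimulatory gene Cd40 (-5.53 ± 0.30) was lowered. Lyve1 cells had 5 raised and 10 lowered M1 members and 12 raised and 8 lowered M2 members (13 and 8 adjusted over the list alone), with Cd163 (5.21 ± 0.19), Mrc1 (3.26 ± 0.15) and the scavenger receptor gene Stab1 (4.26 ± 0.11) raised and Il1b (-3.36 ± 0.37) lowered. C1q cells had 5 raised and 5 lowered M1 members and 9 raised and 4 lowered M2 members (9 and 6 adjusted over the list alone). Trem2 cells had 4 raised and 9 lowered M1 members (5 and 10 adjusted over the list alone) and 11 raised and 5 lowered M2 members (11 and 6 adjusted over the list alone), and classical monocyte-like cells had 11 raised and 4 lowered M1 members and 5 raised and 12 lowered M2 members. In the other 8 classes, 1 to 10 M1 members were raised and 4 to 11 lowered, and 2 to 13 M2 members were raised and 5 to 15 lowered. The fewest lowered in any of them with 1 replicate left out were 1 M1 and 3 M2 members. Without replicate 1, the raised and lowered counts were 1 and 16 M1 members in alveolar cells, 2 and 1 M1 members in C1q cells, 7 and 2 M2 members in C1q cells, 4 and 4 M1 members in Trem2 cells and 12 and 0 M1 members in classical monocyte-like cells (edgeR, 2 lowered at an unadjusted p under 0.05). Without replicate 2, the raised and lowered counts were 1 and 17 M1 members in alveolar cells, 2 and 7 M1 members in Lyve1 cells, 2 and 1 M1 members in C1q cells, 8 and 2 M2 members in C1q cells, 2 and 6 M1 members in Trem2 cells, 10 and 3 M2 members in Trem2 cells and 10 and 2 M1 members in classical monocyte-like cells. Without replicate 3, the raised and lowered counts were 13 and 1 M1 members in classical monocyte-like cells. With no replicate block, the raised and lowered counts were 4 and 3 M1 members in C1q cells, 8 and 1 M2 members in C1q cells, 11 and 3 M2 members in Trem2 cells and 11 and 2 M1 members in classical monocyte-like cells.

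In all, 482 of 752 edgeR tests of a panel gene in a class passed an adjusted p of 0.05, 255 raised and 227 lowered. Members summed, the M2 panel stood above the M1 panel in 11 of 16 classes. Alveolar macrophage-like cells had 14517 ± 2462 CPM of M2 and 616 ± 134 of M1 transcripts, Lyve1 cells 8773 ± 185 and 2007 ± 260.1, and C1q cells 3379 ± 344 and 2864 ± 251. Cluster 11 had 3042 ± 810.2 CPM of M2 and 5523 ± 506 of M1 transcripts, and neutrophil-like cells 2583 ± 397 and 14223 ± 3659. Cluster 13 had 23036 ± 1578 CPM of M2 transcripts, of which Retnla, a resistin-like gene chosen here after its values were seen, gave 19783 ± 1806. Sums follow the few most abundant members and do not weight genes equally.

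**Figure D2:**
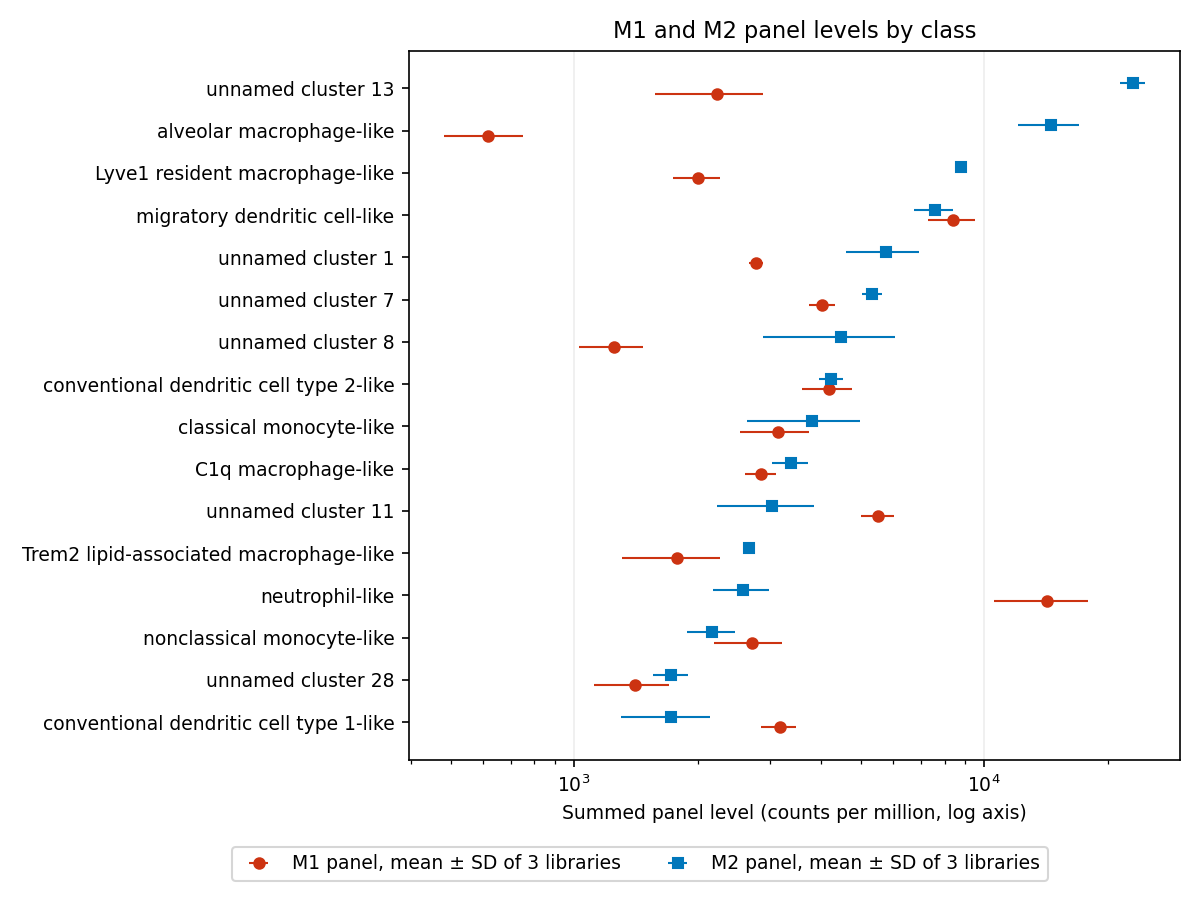
Summed CPM of the M1 and M2 panels in 16 classes on a log axis, with points for the mean and lines for the SD of 3 libraries. The M2 sum is highest in cluster 13 and the M1 sum in neutrophil-like cells, at 14223 CPM.

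**Figure D3:**
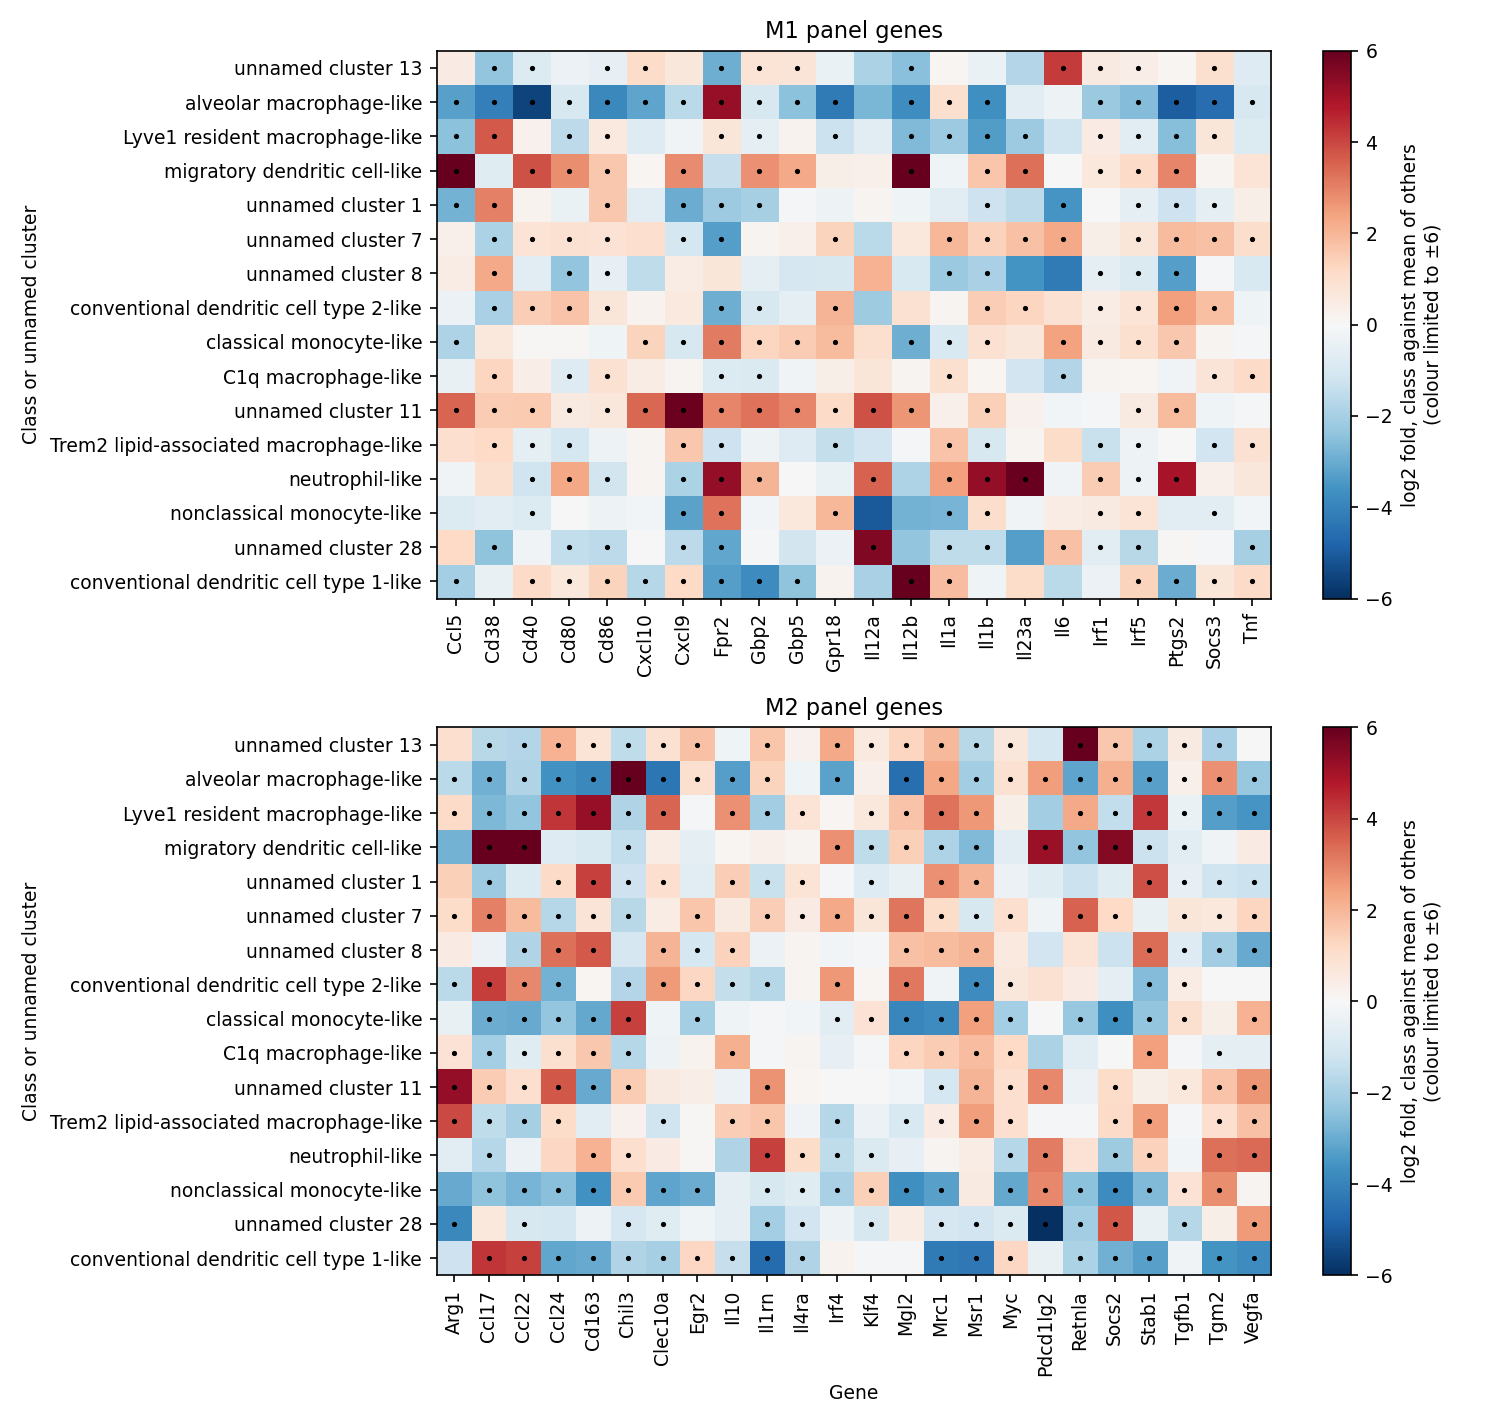
Log2 difference of panel genes in each class from the mean of the other classes, coloured from -6 to 6, with a dot where the adjusted p was under 0.05 (edgeR, 3 libraries per class). Cluster 11 has dots and high values for both Cxcl9 and Arg1.

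The first comparison asked how C1q macrophage-like cells differed from classical monocyte-like cells of the same libraries. A gene is said to have risen where it was higher in the first class named. Values are log2 fold changes ± an approximate standard error (n = 3 libraries per class). That error is the absolute log2 fold change over the square root of the edgeR F statistic. Every gene named by a value was changed the same way in 3 of 3 libraries unless stated. A list's count adjusted over the list alone is given where it differed from the count over all genes. C1q cells carried more of several M2 receptor genes. Of the M2 panel, 12 of 24 rose, 6 fell and 6 did not pass; Mrc1 (4.97 ± 0.33), Mgl2 (4.90 ± 0.44), Stab1 (4.54 ± 0.26) and Cd163 (4.40 ± 0.47) rose and Chil3 (-5.44 ± 0.58) fell. The M1 panel went the other way in most of its called members: 4 of 23 rose, 10 fell and 9 did not pass (5 rose and 10 fell adjusted over the list alone), with the cytokine gene Il6 (-3.94 ± 0.82), Fpr2 (-3.72 ± 0.32) and Gbp2 (-2.03 ± 0.30) lower and the cytokine gene Il1a (1.79 ± 0.48) higher. As lists, neither panel passed (camera adjusted p = 0.0943 for M1 and 0.208 for M2). The M1 panel passed under 3 alternatives, with cluster 11 counted as monocyte-like, no filter on low counts or scaling over all cells (range over alternatives 0.00162 to 0.211). Arg1 was 1.24 ± 0.52 (adjusted p = 0.0386) and Cxcl9 1.07 ± 0.43 (adjusted p = 0.0327), while Il1b at -0.75 ± 0.38 did not pass (adjusted p = 0.0861). Without replicate 1, Il1a was 1.75 (adjusted p = 0.0842), Arg1 1.25 (adjusted p = 0.219) and Cxcl9 0.29 (adjusted p = 0.633), and 2 M1 panel genes rose and 9 fell. Without replicate 2, Il6 was -3.06, Il1a 2.41 and Cxcl9 1.38 (adjusted p = 0.0992). Without replicate 3, Il6 was -5.09, Gbp2 -2.61, Il1a 1.07, Arg1 0.90 (adjusted p = 0.329) and Il1b -0.96 (adjusted p = 0.0152). Arg1 was negative under 4 alternatives, from -2.70 with cluster 11 counted as classical monocyte-like to -0.37 at resolution 0.5. Cxcl9 was -3.43 with cluster 11 counted so, and Il1a -0.20 with genes scaled over all cells.

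Antigen presentation split by class. Of the MHC class II genes, 9 of 9 rose, with H2-Eb1 (4.65 ± 0.40), H2-Aa (4.31 ± 0.38) and H2-Ab1 (4.07 ± 0.36) (camera adjusted p = 8.02e-05, and adjusted p = 0.219 with an estimated correlation). The camera adjusted p was 0.133 with cluster 11 counted as monocyte-like and 0.574 with scaling over all cells, in a range over alternatives of 1.30e-07 to 0.574. Of the MHC class I list, 1 of 12 rose, 10 fell and 1 did not pass (1 rose and 11 fell adjusted over the list alone), with the peptide transporter gene Tap1 (-1.38 ± 0.19) and H2-T23 (-1.07 ± 0.16) among them (camera adjusted p = 0.00161, and adjusted p = 0.319 with an estimated correlation). Of the interferon response genes, 17 of 17 fell, with Ms4a4c (-4.98 ± 0.51) and Ifi205 (-4.84 ± 0.44) (camera adjusted p = 9.40e-05, and adjusted p = 0.319 with an estimated correlation). Without a replicate block, 5 of 17 fell (9 at an unadjusted p under 0.05). Of the glycolysis and hypoxia genes, 1 of 22 rose, 15 fell and 6 did not pass (1 rose and 16 fell adjusted over the list alone), with the lactate exporter gene Slc16a3 (-2.68 ± 0.19) and Ndrg1 (-3.65 ± 0.41) (camera adjusted p = 9.40e-05, and adjusted p = 0.219 with an estimated correlation). Without replicate 3, Ms4a4c was -5.76 and Ifi205 -5.75.

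Chemokine and uptake genes were mostly higher in C1q cells. Of the chemokine list, 13 of 21 rose, 2 fell and 6 did not pass (14 rose and 2 fell adjusted over the list alone), with Cxcl13 (6.64 ± 1.10) and Ccl12 (5.39 ± 0.56) (camera adjusted p = 0.00505, and adjusted p = 0.219 with an estimated correlation, range over alternatives 4.99e-05 to 0.461). Of the uptake receptors, 11 of 16 rose, 2 fell and 3 did not pass, with the apoptotic-cell receptor gene Mertk (5.10 ± 0.30) and Stab1 (4.54 ± 0.26) (camera adjusted p = 0.0223, and adjusted p = 0.319 with an estimated correlation, range over alternatives 0.000476 to 0.577). Without a replicate block, 7 of these rose and 1 fell. The chemokine and uptake receptor calls were lost with cluster 11 counted as monocyte-like and with scaling over all cells, and that of uptake receptors also at resolution 0.5. Nearly all cell cycle genes were higher: 19 of 20 rose and 1 fell, with the mitotic kinase gene Cdk1 (5.56 ± 0.53) and Cenpf (4.99 ± 0.68) (camera adjusted p = 8.02e-05, and adjusted p = 0.319 with an estimated correlation). Without a cycling cluster of 1085 cells in the class, the camera adjusted p was 0.285, and the call was also lost with doublets kept and at resolution 0.5 (range 3.84e-10 to 0.285). Of the lysosome and protease genes, 9 of 21 rose, 4 fell and 8 did not pass, with the protease gene Lgmn (2.06 ± 0.18) higher (camera adjusted p = 0.380). Of the immune regulation genes, 4 of 15 rose, 6 fell and 5 did not pass (6 rose and 6 fell adjusted over the list alone), with the cytokine gene Il10 (2.25 ± 0.43) and Siglece (1.59 ± 0.27) higher and Cd274 (-0.85 ± 0.25) lower (camera adjusted p = 0.380). Of the immediate early and stress genes, 5 of 16 rose, 1 fell and 10 did not pass, with Hspa1a (1.55 ± 0.31) and Egr1 (1.52 ± 0.40) (camera adjusted p = 0.688). Without replicate 1, Egr1 was 1.29 (adjusted p = 0.0973) and Cd274 -0.94 (adjusted p = 0.0534), and 8 uptake receptor genes rose and 1 fell, 3 lysosome and protease genes rose and 2 fell, 2 immune regulation genes rose and 4 fell and 3 immediate early and stress genes rose and 1 fell. Without replicate 2, 12 chemokine genes rose and 1 fell, 7 uptake receptor genes rose and 1 fell, 4 lysosome and protease genes rose and 2 fell and 2 immune regulation genes rose and 6 fell. Without replicate 3, 11 uptake receptor genes rose and 4 fell.

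Outside the lists, Lyzl4 (6.19 ± 0.38), Spats2 (6.04 ± 0.32) and Ms4a14 (5.98 ± 0.38) were the most raised, with C1qc (5.95 ± 0.38), itself a marker that names the class, and Nfe2 (-7.83 ± 0.28), Pi16 (-7.42 ± 0.49), Bmx (-7.08 ± 0.40) and Hpse (-6.12 ± 0.36) the most lowered. Of the sort genes, Itgam (-1.28 ± 0.18) and Ptprc (-1.44 ± 0.13) fell and Fcgr1 was -0.41 ± 0.38 (adjusted p = 0.364). B cell list UMIs were in 32.8% ± 9.68 (unthinned 76.3%) of thinned C1q cells and 21.6% ± 12.3 (unthinned 66.3%) of monocyte-like cells, and fibroblast list UMIs in 31.5% ± 3.08 (unthinned 63.0%) and 2.74% ± 1.21 (unthinned 13.8%). In the same order, the neutrophil list gave 12.0% ± 1.37 (unthinned 45.9%) and 46.6% ± 13.5 (unthinned 91.4%), the T or NK cell list 8.66% ± 0.411 (unthinned 28.3%) and 0.703% ± 0.246 (unthinned 5.75%) and the epithelial list 7.29% ± 0.853 (unthinned 25.6%) and 1.17% ± 0.685 (unthinned 7.43%). The plasmacytoid dendritic cell list gave 46.8% ± 4.18 and 26.4% ± 3.17 of thinned cells. Of 14310 genes not used to cluster, 8526 changed (edgeR adjusted p under 0.05), 5125 up and 3401 down. Leave-one-out gave 5716 without replicate 1, 6202 without replicate 2 and 9386 without replicate 3. The share up, 60.1%, was 49.9 to 61.8% over alternatives and 49.9% without replicate 3, so an excess of raised genes is not stable. Without replicate 2, Pi16 was -8.23. Without replicate 3, Hpse was -6.90 and Fcgr1 -0.61 (adjusted p = 0.0142). The classes were defined from the same cells, so these genes are not independent evidence that the classes differ.

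The second comparison set alveolar macrophage-like cells, the macrophages of the air spaces, against C1q cells. Cluster 14 gave this class 2408, 2369 and 29 cells and cluster 15 gave it 64, 31 and 1728 cells in replicates 1, 2 and 3. Replicate 3 and the other replicates thus entered the class mostly through different clusters. Alveolar cells carried fewer M1 panel transcripts: 1 of 23 rose, 16 fell and 6 did not pass, with Fpr2 (5.70 ± 0.34) higher and the costimulatory and activation genes Cd40 (-5.56 ± 0.32), Cd38 (-5.05 ± 0.66), Socs3 (-4.98 ± 0.30) and Cd86 (-4.45 ± 0.28) lower (camera adjusted p = 0.00121, and adjusted p = 0.219 with an estimated correlation). The M2 panel divided: 8 of 24 rose, 13 fell and 3 did not pass, with Chil3 (7.65 ± 0.64) higher and Mgl2 (-5.46 ± 0.45), Stab1 (-5.39 ± 0.27), Cd163 (-5.14 ± 0.47) and Il10 (-5.11 ± 0.49) lower (camera adjusted p = 0.311). Of the MHC class II genes, 9 of 9 fell, with H2-Eb1 (-5.29 ± 0.41), H2-Aa (-4.89 ± 0.39) and H2-Ab1 (-4.60 ± 0.37) (camera adjusted p = 0.000260, and adjusted p = 0.221 with an estimated correlation). Interferon response genes moved the same way: 17 of 17 fell, with Slfn5 (-4.80 ± 0.40) and Oasl2 (-4.33 ± 0.60) (camera adjusted p = 0.0101, and adjusted p = 0.645 with an estimated correlation, range over alternatives 7.80e-08 to 0.148). Without a replicate block the camera adjusted p of that list was 0.148, and with doublets kept 0.0793. For MHC class I, 8 of 12 fell and 4 did not pass, with Nlrc5 (-2.64 ± 0.21) and H2-Q7 (-2.31 ± 0.21) (camera adjusted p = 0.0833). That list passed under 6 alternatives, thinned cells and leaving out replicate 2 among them (range over alternatives 0.00751 to 0.147). Arg1 was -2.32 ± 0.50, Cxcl9 -1.67 ± 0.42, Il1b -3.57 ± 0.42 and Mrc1 0.73 ± 0.28 (adjusted p = 0.0230). Without replicate 1, Cxcl9 was -1.13 (adjusted p = 0.0519) and Mrc1 0.84 (adjusted p = 0.0512), and 4 M2 panel genes rose and 11 fell and 5 MHC class I genes fell. Without replicate 2, Arg1 was -3.11, Cxcl9 -1.53 (adjusted p = 0.0582) and Mrc1 0.89 (adjusted p = 0.0709). Without replicate 3, Arg1 was -0.83 (adjusted p = 0.162), and 4 M1 panel genes rose and 16 fell and 2 MHC class I genes rose and 6 fell.

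Chemokine genes were lower in alveolar cells: 1 of 21 rose, 18 fell and 2 did not pass, with Cxcl13 (-6.08 ± 1.04) and Ccl12 (-5.89 ± 0.56) (camera adjusted p = 0.000260, and adjusted p = 0.167 with an estimated correlation). Immediate early and stress genes were lower as well: 14 of 16 fell and 2 did not pass, with the heat shock genes Hspa1a (-4.56 ± 0.36) and Hspa1b (-4.05 ± 0.35) (camera adjusted p = 6.96e-06, and adjusted p = 0.219 with an estimated correlation). Lysosome and protease genes split: 5 of 21 rose, 7 fell and 9 did not pass, with the cathepsin genes Ctsk (5.53 ± 0.34) and Ctsd (3.21 ± 0.38) higher (camera adjusted p = 0.829). Of the glycolysis and hypoxia genes, 10 of 22 rose, 5 fell and 7 did not pass, with the lipid droplet gene Hilpda (2.28 ± 0.25) higher and Hk1 (-1.76 ± 0.16) lower (camera adjusted p = 0.341). For immune regulation, 6 of 15 rose, 6 fell and 3 did not pass, with Cd274 (3.27 ± 0.27) higher (camera adjusted p = 0.858). The median log2 change of that list was -0.09 and its mean 0.27, opposite in sign. Of the uptake receptors, 6 of 16 rose, 8 fell and 2 did not pass (6 rose and 9 fell adjusted over the list alone), and the list did not pass (camera adjusted p = 0.357). Among cell cycle genes, 2 of 20 fell and 18 did not pass (no member passed adjusted over the list alone), with Hmgb2 at -0.63 ± 0.21 and Mcm6 at -0.62 ± 0.24 (camera adjusted p = 0.808). Unadjusted, 3 fell at p under 0.05, and DESeq2 called 2. As a list, cell cycle genes were called higher with doublets kept (camera adjusted p = 0.000422) and at resolution 0.5 (0.00603). They were also called higher with cycling cluster 9 of the C1q class left out (camera adjusted p = 0.00931), and lower with scaling over all cells (0.0141). Leaving out cluster 9 takes cycling cells from the C1q side only, since cycling cluster 23 (369 cells) of alveolar cells stayed. That setting moves the list up in alveolar cells by construction. Without replicate 1, Cxcl13 was -6.80, Hmgb2 -0.57 (adjusted p = 0.102) and Mcm6 -0.61 (adjusted p = 0.15), and 0 cell cycle genes passed (edgeR, 0 rose and 1 fell at an unadjusted p under 0.05). Without replicate 2, Mcm6 was -0.62 (adjusted p = 0.156). Without replicate 3, Hmgb2 was -0.42 (adjusted p = 0.149), and 3 cell cycle genes rose and 2 fell. With no replicate block, 1 cell cycle gene fell. Hmgb2 was 0.34 with the cycling cluster left out, and Mcm6 0.15 at resolution 0.5.

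Outside the lists, Vstm2a (8.22 ± 0.37), Perp (8.01 ± 0.31), Mcoln3 (7.98 ± 0.27) and Slc9a2 (7.79 ± 0.40) rose most and Tmem119 (-6.53 ± 0.40), Adam19 (-6.48 ± 0.35), Rasgrp1 (-6.34 ± 0.30) and Blnk (-6.34 ± 0.34) fell most. Itgam fell by 4.99 ± 0.21 on the log2 scale, Fcgr1 was -1.60 ± 0.39 and Ptprc 0.46 ± 0.13 (adjusted p = 0.00193). Epithelial list UMIs were in 17.9% ± 8.94 (unthinned 69.8%) of thinned alveolar cells and 7.29% ± 0.853 (unthinned 25.6%) of C1q cells, and fibroblast list UMIs in 2.53% ± 1.24 (unthinned 22.7%) and 31.5% ± 3.08 (unthinned 63.0%). In that order, the B cell list gave 0.899% ± 0.499 (unthinned 10.0%) and 32.8% ± 9.68 (unthinned 76.3%), the T or NK cell list 0.309% ± 0.283 (unthinned 2.82%) (0.141, 0.149 and 0.636% by replicate) and 8.66% ± 0.411 (unthinned 28.3%) and the endothelial list 10.1% ± 0.244 (unthinned 60.0%) and 5.88% ± 0.714 (unthinned 27.3%). Plasmacytoid dendritic cell list UMIs were in 7.17% ± 0.875 and 46.8% ± 4.18 of thinned cells. Among 14310 genes not used to cluster, 8431 changed in edgeR (adjusted p under 0.05), 3954 of them up, and leave-one-out gave 5649 without replicate 1, 6250 without replicate 2 and 9932 without replicate 3. The share up, 46.9%, was 41.2 to 52.9% over alternatives and 52.5% without replicate 3, so the majority direction turned. Without replicate 2, Ptprc was 0.46 (adjusted p = 0.0558).

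The third comparison set Trem2 cells against C1q cells. Lysosome and protease genes were higher in Trem2 cells: 16 of 21 rose, 1 fell and 4 did not pass, with the cathepsin genes Ctsd (3.26 ± 0.38) and Ctsk (2.92 ± 0.31) (camera adjusted p = 7.73e-11, and adjusted p = 0.0251 with an estimated correlation). Glycolysis and hypoxia genes were higher: 14 of 22 rose and 8 did not pass (14 rose and 1 fell adjusted over the list alone), with the glycolytic enzyme genes Pgam1 (1.63 ± 0.20) and Pkm (1.33 ± 0.23) (camera adjusted p = 3.96e-05, and adjusted p = 0.0944 with an estimated correlation). MHC class II genes were lower: 9 of 9 fell, with the class II transactivator gene Ciita (-1.84 ± 0.26), H2-Eb1 (-1.77 ± 0.36) and H2-Ab1 (-1.56 ± 0.33) (camera adjusted p = 6.25e-06, and adjusted p = 0.128 with an estimated correlation). Of the immediate early and stress genes, 12 of 16 fell and 4 did not pass (14 fell adjusted over the list alone), with Btg2 (-1.39 ± 0.20) and Jun (-1.35 ± 0.28) (camera adjusted p = 1.98e-05, and adjusted p = 0.226 with an estimated correlation). Without a replicate block, 7 of these fell. Of the cell cycle genes, 15 of 20 fell and 5 did not pass, with Nusap1 (-3.97 ± 0.39) and Ube2c (-3.53 ± 0.68) (camera adjusted p = 7.26e-05, and adjusted p = 0.401 with an estimated correlation). Without the cycling cluster of the C1q class, the list was higher in Trem2 cells (camera adjusted p = 0.0316, range over alternatives 1.45e-29 to 0.0707), with Nusap1 at 0.96 and Ube2c at 0.99. That setting takes cycling cells from the C1q side only, so it moves the list up in Trem2 cells by construction. The list's direction also turned with doublets kept (0.0707) and at resolution 0.5 (4.29e-06). Of all camera calls in the 3 comparisons, lysosome and protease genes in Trem2 cells were the only one kept with an estimated correlation. Without replicate 1, 7 immediate early and stress genes fell and 7 cell cycle genes fell.

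In the panels, Trem2 cells were higher in Arg1 (2.88 ± 0.41), the angiogenic factor gene Vegfa (2.15 ± 0.29) and Chil3 (1.83 ± 0.49) and lower in Cd163 (-2.15 ± 0.42) and Mgl2 (-2.07 ± 0.38): of the M2 panel, 7 of 24 rose, 6 fell and 11 did not pass (camera adjusted p = 0.727). Of the M1 panel, 2 of 23 rose, 7 fell and 14 did not pass, with Socs3 (-1.78 ± 0.26), Irf1 (-1.42 ± 0.26) and Cd86 (-1.11 ± 0.25) lower and Cxcl9 (1.36 ± 0.41) higher (camera adjusted p = 0.279). Il1b was -1.02 ± 0.38 (adjusted p = 0.0355) and Mrc1 -0.98 ± 0.28 (adjusted p = 0.00619). Without replicate 1, Il1b was -1.21 (adjusted p = 0.190), Chil3 1.41 (adjusted p = 0.0999) and Mrc1 -0.81 (adjusted p = 0.114), and 1 M1 panel gene rose and 4 fell and 3 M2 panel genes rose and 3 fell. Without replicate 2, Cxcl9 was 1.07 (adjusted p = 0.271), Il1b -1.11 (adjusted p = 0.0794), Chil3 2.07 (adjusted p = 0.0527) and Mrc1 -0.89 (adjusted p = 0.136), and 4 M1 panel genes fell and 0 rose (edgeR, 0 at an unadjusted p under 0.05) and 4 M2 panel genes rose and 2 fell. Without replicate 3, Il1b was -0.68 (adjusted p = 0.116), and 4 M1 panel genes rose and 6 fell. At resolution 0.5 Cd163 was 0.04. With the UMI minimum of replicate 3 in every library, Cxcl9 was -0.000807.

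Immune regulation genes were mixed in Trem2 cells: 5 of 15 rose, 2 fell and 8 did not pass, with Il18bp, an interleukin 18 inhibitor gene (2.41 ± 0.31), Cd200r1 (2.00 ± 0.24) and Cd274 (1.81 ± 0.26) higher (camera adjusted p = 0.171, range over alternatives 0.00564 to 0.330). Of the chemokine genes, 4 of 21 rose, 2 fell and 15 did not pass, with Ccl6 (2.32 ± 0.25) higher and Cxcl13 (-2.53 ± 0.88) lower (camera adjusted p = 0.437, range over alternatives 0.0322 to 0.845). Of the uptake receptors, 3 of 16 rose, 1 fell and 12 did not pass, with the fatty acid receptor gene Cd36 (1.5 ± 0.28) higher (camera adjusted p = 0.727, direction Up, though the median was -0.14 and the mean -0.06). Of the MHC class I list, 1 of 12 rose and 11 did not pass (no member passed adjusted over the list alone), with H2-D1 (0.39 ± 0.14) higher (camera adjusted p = 0.941). Of 17 interferon response genes, edgeR called 0, 1 fell at an unadjusted p under 0.05, and DESeq2 called 0 (camera adjusted p = 0.941), with a median of 0.05 and a mean of -0.02. At resolution 0.5, the interferon response (camera adjusted p = 4.42e-05), MHC class I (0.00291) and chemokine lists (0.0322) were called higher. The Trem2 class of that setting held 94.3% of the cluster 11 cells, so these calls are not for the same cells. The immune regulation list was called with only the 2 classes in the fit and with scaling over all cells. With no replicate block, 3 chemokine genes rose and 1 fell. Without replicate 1, Cxcl13 was -2.26 (adjusted p = 0.215) and H2-D1 0.57 (adjusted p = 0.0979), and 3 immune regulation genes rose and 1 fell and 3 chemokine genes rose and 0 fell (edgeR, 1 at an unadjusted p under 0.05). Without replicate 2, Cxcl13 was -3.31 (adjusted p = 0.0695) and H2-D1 0.38 (adjusted p = 0.268), and 3 immune regulation genes rose and 1 fell and 1 chemokine gene rose and 0 fell (edgeR, 2 at an unadjusted p under 0.05). Without replicate 3, 7 chemokine genes rose and 4 fell, 3 uptake receptor genes rose and 4 fell and 2 MHC class I genes rose and 2 fell.

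Outside the lists, Rnf128 (4.09 ± 0.42), Ahnak2 (3.86 ± 0.28), Cd200r4 (3.72 ± 0.34) and Slc6a8 (3.23 ± 0.28) rose most and Serpinf1 (-2.96 ± 0.33), Lifr (-2.58 ± 0.37), Sult1a1 (-2.44 ± 0.29) and Ildr1 (-2.40 ± 0.32) fell most. Fcgr1 was -0.13 ± 0.39 (adjusted p = 0.829, up in 1 of 3 libraries), Itgam 0.15 ± 0.17 (adjusted p = 0.547, up in 2 of 3) and Ptprc -0.50 ± 0.13. T or NK cell list UMIs were in 24.6% ± 5.86 (unthinned 59.0%) of thinned Trem2 cells and 8.66% ± 0.411 (unthinned 28.3%) of C1q cells. B cell list UMIs were in 8.50% ± 5.32 (unthinned 37.0%) and 32.8% ± 9.68 (unthinned 76.3%), and fibroblast list UMIs in 11.8% ± 2.64 (unthinned 42.9%) and 31.5% ± 3.08 (unthinned 63.0%). In all, 4731 of 14310 genes not used to cluster changed (edgeR, adjusted p under 0.05), 2154 up and 2577 down, and leave-one-out gave 1769 without replicate 1, 1990 without replicate 2 and 5229 without replicate 3. Without the library block 2976 changed. The share up, 45.5%, was 42.5 to 60.0% over alternatives, highest without replicate 1, so the majority direction turned under some of them. Without replicate 1, Ptprc was -0.31 (adjusted p = 0.396). Without replicate 2, Ptprc was -0.47 (adjusted p = 0.107). Without replicate 3, Cd200r4 was 4.43 and Serpinf1 -2.28.

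Within a class, M1 panel genes were weakly correlated with each other. Across single cells thinned to 2000 UMIs, the mean Pearson correlation over pairs of M1 genes was highest in cluster 11 at 0.0749 ± 0.0135 (SD, n = 3 libraries) and was 0.0595 ± 0.0158 in cDC1 cells and 0.0363 ± 0.00421 in C1q cells, where random lists matched for level gave 0.000902. Pairs of M2 genes gave 0.0144 ± 0.00262 in C1q cells, 0.0537 ± 0.0162 in neutrophil-like cells and 0.0594 ± 0.0286 in cluster 28. By replicate, nonclassical monocyte-like cells gave 0.00591, 0.000169 and 0.00230, above 48.4 to 78.1% of random lists, and classical monocyte-like cells 0.00133, 0.0120 and 0.00229, above 62.1 to 100%. Trem2 cells gave -0.00203, 0.0157 and 0.0163, above 24 to 100%, and the mean in alveolar cells was 0.00290 ± 0.00117, above 68.2 to 84.5%. Between an M1 and an M2 gene the mean was 0.00910 ± 0.00223 in C1q cells, against 0.000847 for random list pairs, 0.0243 ± 0.00136 in cDC1 cells and 5.97e-05, -0.00684 and -0.00131 in cluster 1 by replicate, above 1.70 to 45.7% of random list pairs. In the 3 libraries the C1q value between panels exceeded 99.8 to 100% of 1000 random list pairs. In simulated cells, 2 modules planted independently of each other also exceeded 100% of random list pairs, at 0.00890. The percentile between panels therefore does not show that the panels go together in the same cells. Genes are not independent replicates, and an exact sign-flip test over 3 libraries cannot go below p = 0.25 (two-sided), so no p is given.

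Arg1 and Cxcl9 were rarely found in the same cluster 11 cell of replicate 3. In replicate 3, 149 of 2461 thinned cells had an Arg1 UMI (6.05%) and 300 a Cxcl9 UMI (12.2%), and 1 had both, where 18.2 would be found if they were independent (ratio 0.0551, exact 95% interval 0.00139 to 0.306). Replicates 1 and 2 had too few cells, with 1 and 0 found with both genes against 0.368 and 0.388 expected. At 4000 UMIs 8 cells had both against 25.5 expected (ratio 0.314), and at 1000 UMIs 0 against 10.8. In the same cells Arg1 was found with Vegfa at 2.79 times, with Mrc1 at 1.71 times and with Il1b at 1.13 times the number if independent. Mrc1 with Cxcl9 in cluster 11 gave 0.718 ± 0.311 (SD, n = 3). Alveolar macrophage-like cells had an Arg1 UMI in 0.196% (0.0534 to 0.501%) of thinned cells in replicate 3, with a median depth of 25182 UMIs against 18615 in cluster 11. Unthinned, an Arg1 UMI was in 1.71, 2.58 and 13% of cluster 11 cells and 0.528, 0.892 and 2.59% of alveolar cells in replicates 1, 2 and 3. A Cxcl9 UMI was in 23.9% and 6.98% (means over 3 libraries). Nos2 with Il1b gave a ratio of 0.570 in cluster 11 of replicate 3 only, from 3 cells with both, and the other Nos2 pairs had too few cells for a ratio in the classes tested.

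Cycling transcripts were most frequent in cDC2 and cDC1 cells. The share of thinned cells with at least 2 of 10 cell cycle genes was 16.2% ± 0.883 in cDC2 and 9.69% ± 1.49 in cDC1 cells (SD, n = 3), 6.32% ± 2.12 in alveolar and 5.70% ± 2.16 in C1q cells, 2.36% ± 0.290 in Trem2 cells and 1.33% ± 0.773 in cluster 11. It was 0.538% ± 0.336 in classical monocyte-like and 0.424% ± 0.142 in Lyve1 cells. Unthinned values were 42.6%, 34.7%, 27.2%, 13.3%, 24.3%, 11.6%, 7.44% and 8.23% in the same order, with 3.74, 6.13 and 12.4% by replicate in classical monocyte-like cells. Migratory dendritic cell-like cells had 3.60% ± 1.06 (unthinned 18.7%) and nonclassical monocyte-like cells 0.294% ± 0.509 (replicate 2 only, unthinned 2.37%), and no thinned neutrophil-like cell passed. Median depths of cDC2 cells were 18935, 20878 and 19369 UMIs in replicates 1, 2 and 3.

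Transcripts of marker lists for cells that the sort should leave out were present. Some of these genes were high in the sorted classes themselves, so the sums do not measure such cells. Siglech of the plasmacytoid dendritic cell list was a top gene of cluster 4, a Lyve1 cluster. Inmt of the fibroblast list was a top gene of cluster 6, a C1q cluster. Neutrophil list UMIs were in 46.6% of thinned classical monocyte-like cells. Summed over each list and all kept cells, neutrophil genes gave 329.8 ± 72.9 CPM (SD, n = 3), fibroblast genes 225 ± 46.0, B cell genes 159.7 ± 92.8, epithelial genes 86.9 ± 36.8, T or NK cell genes 60.8 ± 28.9 and endothelial genes 42.8 ± 6.69. Plasmacytoid dendritic cell genes gave 291 ± 64.1, erythroid or platelet genes 3.50 ± 1.81, eosinophil genes 2.65 ± 1.37 and basophil or mast cell genes 1.94 ± 0.917. Melanoma genes gave 8.58, 6.62 and 67.4 CPM in replicates 1, 2 and 3. The naming lists gave 12129.7 ± 1119 CPM for C1q, 3741 ± 1541 for Trem2, 1485 ± 234 for alveolar macrophage, 1460.0 ± 269.7 for classical monocyte and 875 ± 325 for Lyve1 genes. Those for cDC2, cDC1, nonclassical monocyte and migratory dendritic cell genes were 803 ± 186, 777 ± 257, 501 ± 40.0 and 158 ± 10.7.

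The melanocyte genes were higher in Trem2 cells than in C1q cells of each library. By replicate, a UMI of the melanoma list was found in 2.19, 3.96 and 7.48% of thinned Trem2 cells and 0.184, 0.241 and 1.25% of C1q cells (unthinned 10.1, 16.5 and 42.9% and 0.980, 1.56 and 9.31%). Classical monocyte-like cells had 0.0647, 0.0616 and 0.649% (unthinned 0.903, 0.735 and 3.79%). Cluster 28 had 16.7, 0.862 and 13.7%, high in replicates 1 and 3 only, with median depths of 14403.5, 18174.5 and 24422 UMIs (unthinned 14.3, 1.49 and 17.8%). Dct, a melanin synthesis gene, was 7.77, 27.0 and 20.4 CPM in Trem2 cells and 0.0694, 0.619 and 4.43 in C1q cells by replicate. In replicate 2, 0 of 188 migratory dendritic cell-like cells had one, with an exact upper bound of 1.94%. Dct was chosen here after its values were seen.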

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

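The test of melanoma transcripts in Trem2 lipid-associated macrophage-like cells was chosen only after the result was seen. Signals outside the comparisons were 195 B cell-like cells and 141 endothelial cell-like cells, named classes with under 50 cells in a library. The sort for CD64 and CD11b should remove both. A further signal lay in barcodes left out of the comparisons: 44 barcodes called as doublets had at least 3 UMIs of the melanoma list, 2, 12 and 30 in replicates 1, 2 and 3.

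Melanoma transcripts (Pmel, Dct, Tyrp1, Mlana, Tyr, Slc45a2 and Cdh19) were found in sorted CD64+CD11b+ cells, a gate that should remove melanoma cells. Free RNA in equal amounts in every droplet is argued against for Trem2 cells, since their share with a melanoma list UMI was at least 5.99 times that of C1q macrophage-like cells in each library (ratios 11.9, 16.4 and 5.99, intervals apart). Over all classes, the ratio of the highest to the lowest share was at least 2.48 in each library. The lowest classes had no such cell (taken as 3), so this ratio alone cannot decide on equal free RNA. The intervals of these classes, picked as extremes, were apart. Lower bounds of the highest were 8.62, 2.40 and 6.77% and upper bounds of the lowest 2.91, 1.94 and 2.76% by replicate. Doublets with melanoma cells stay open as a candidate explanation, since the share of called doublets with at least 3 such UMIs was 0.481, 1.43 and 1.23 times that of other barcodes (highest 1.43), with upper bounds of 2.59, 3.30 and 1.92. No biological explanation was tested, since all libraries are in 1 group.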

How the results depend on the processing

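Tests under the UMI minimum of replicate 3, with cluster 11 counted as classical monocyte-like, with cluster 9 left out and for cluster 11 against cluster 17 were chosen only after the result was seen. Of 2472 values of named genes under alternatives, 2334 kept their direction and their side of the threshold, 107 lost the call, 12 gained it and 19 reversed. Reversed means an opposite sign where the main setting, the alternative or both passed, so a reversed value need not pass itself. Of 660 camera results for lists, the numbers were 621, 16, 15 and 8, where a list or gene uncalled under both settings counts as kept even if its sign turned. Of 1191 levels, shares and correlations, 1060 stayed within the SD over libraries (numbers of genes or lists within 1.5-fold, the Arg1 and Cxcl9 ratio within its interval) and 131 moved further. RLE in place of TMM kept 128 of 128 named gene values and shifted the median log2 change by 0.03, -0.08 and -0.02, and DESeq2 kept 127 and lost 1.

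For C1q macrophage-like against classical monocyte-like cells, Arg1 reversed to -0.54 with doublets kept, -2.70 with cluster 11 counted as monocyte-like, -0.37 at resolution 0.5 and -2.07 with scaling over all cells. Cxcl9 reversed to -3.43 with cluster 11 so counted and -2.10 with scaling over all cells, where Il1a was -0.20. In Trem2 cells, Cxcl9 was -0.000807 with the UMI minimum of replicate 3, and Cd163 0.0362 at resolution 0.5. With doublets kept, cluster 9 left out and resolution 0.5 in this order, Nusap1 in Trem2 cells was 0.59, 0.96 and 2.34, Ube2c 1.27, 0.99 and 0.78, and Hmgb2 in alveolar cells 0.46, 0.34 and 0.39. Among these, only Nusap1 at resolution 0.5 (edgeR adjusted p = 0.000215) and Hmgb2 with doublets kept (0.00601) passed. The cell cycle list turned up in the same settings, with camera adjusted p of 0.0707, 0.0316 and 4.29e-06 in Trem2 cells (range over alternatives 1.45e-29 to 0.0707) and 0.000422, 0.00931 and 0.00603 in alveolar cells (0.000422 to 0.915). Leaving out cluster 9 takes cycling cells from the C1q class only, so a move up is built into that setting. Mcm6 in alveolar cells was 0.15 at resolution 0.5 and did not pass (edgeR adjusted p = 0.598). At that resolution MHC class I (camera adjusted p = 0.00291, range 0.00291 to 0.991) and interferon response (4.42e-05, range 4.42e-05 to 0.991) turned up in Trem2 cells and 8 lists were called. The Trem2 class then held 94.3% of the cluster 11 cells and was 25.9% of replicate 3, against 11.7% in the main setting. Its calls at this resolution therefore describe a merged class, not the Trem2 cells of the main setting alone. The cause of the other changes was not tested.

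Thinned to 2000 UMIs, which leaves fewer counts, 5392 genes changed in C1q against monocyte-like, 5434 in alveolar against C1q and 2819 in Trem2 against C1q cells. In the last, 2976 changed without a replicate block and 1769 to 5229 with 1 replicate left out, and 3003 to 5442 changed for cluster 11 against cluster 17. At 1000 and 4000 UMIs, the Arg1 and Cxcl9 ratio in cluster 11 of replicate 3 was 0 and 0.314, the correlation between panels averaged over classes 0.00698 and 0.0123, and the share of cycling cells averaged over classes 2.42 and 5.31%. The share of cells in a named class was 71.5% with doublets kept, 94.2% at resolution 0.5, 66.2% with scaling over all cells, 72.7% with a stricter filter and 71.4% with tested lists among the clustering genes. Camera was not run with DESeq2.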

Other observations

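The comparison of cluster 11 with cluster 17, and the tests of separate cells and of free RNA for Arg1 in replicate 3, were chosen only after the result was seen. Cluster 17 is a cluster of classical monocyte-like cells, and cluster 11 carried more antigen presentation and chemokine transcripts than it did. Of the MHC class II genes, 9 of 9 rose, with H2-Eb1 (4.52 ± 0.44) as log2 fold change ± SE (camera adjusted p = 4.78e-11, and adjusted p = 0.0135 with an estimated correlation). Chemokine genes were higher: 16 of 21 rose, 1 fell and 4 did not pass (16 rose and 2 fell adjusted over the list alone), with Cxcl9 (6.33 ± 0.57), Ccl24 (5.69 ± 0.57), Ccl5 (5.01 ± 0.74) and Ccl17 (4.26 ± 0.49) (camera adjusted p = 1.37e-07, and adjusted p = 0.00993 with an estimated correlation). Of the M2 panel, 14 of 24 rose, 2 fell and 8 did not pass (15 rose and 2 fell adjusted over the list alone), with Arg1 (5.35 ± 0.53), Socs2 (4.43 ± 0.43) and Mrc1 (2.53 ± 0.28) higher (camera adjusted p = 9.01e-06, and adjusted p = 0.00193 with an estimated correlation). Of the M1 panel, 9 of 23 rose, 4 fell and 10 did not pass (10 rose and 4 fell adjusted over the list alone), with Il12b (5.21 ± 1.09) higher and Il6 (-2.57 ± 0.81) lower. For this panel camera gave adjusted p = 0.0813, and 0.0342 without replicate 2 (range over alternatives 0.0342 to 0.0813). Il1b was 0.49 ± 0.40 (adjusted p = 0.365), Cd274 2.28 ± 0.24 and Fcgr1 0.51 ± 0.34 (adjusted p = 0.253). Without replicate 1, Cxcl9 was 5.48, Ccl17 3.53 and Il6 -2.61 (adjusted p = 0.114), and 5 M1 panel genes rose and 0 fell (edgeR, 2 at an unadjusted p under 0.05). Without replicate 2, Il12b was 4.29 and Il6 -2.06 (adjusted p = 0.235), and 13 M2 panel genes rose and 1 fell and 6 M1 panel genes rose and 0 fell (edgeR, 1 at an unadjusted p under 0.05). Without replicate 3, Ccl17 was 4.86, Il12b 6.00 and Fcgr1 0.55 (adjusted p = 0.0339), and 15 chemokine genes rose and 2 fell and 16 M2 panel genes rose and 4 fell. With no replicate block, 8 M1 panel genes rose and 2 fell, and 13 M2 panel genes rose and 1 fell.

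Uptake receptors were higher in cluster 11, where 9 of 16 rose, 1 fell and 6 did not pass (9 rose and 2 fell adjusted over the list alone), with Mertk (4.03 ± 0.29) and Axl (3.24 ± 0.23), receptors for apoptotic cells (camera adjusted p = 0.000806, and adjusted p = 0.0648 with an estimated correlation). Of the interferon response genes, 6 of 17 rose and 11 did not pass (7 rose adjusted over the list alone), with Ifit2 (2.01 ± 0.69) and Ifit1 (1.93 ± 0.55) (camera adjusted p = 0.329). MHC class I genes were higher in part: 7 of 12 rose and 5 did not pass (8 rose adjusted over the list alone) (camera adjusted p = 0.0199, and adjusted p = 0.512 with an estimated correlation). The list lost its call without replicate 2 (adjusted p = 0.0564, range over alternatives 4.24e-05 to 0.0564). Of the lysosome and protease genes, 11 of 21 rose, 2 fell and 8 did not pass (13 rose and 2 fell adjusted over the list alone) (camera adjusted p = 0.0240, and adjusted p = 0.524 with an estimated correlation). This call was lost, with adjusted p of 0.0519 without a replicate block and 0.0707 without replicate 2 (range 0.00479 to 0.0707). Of the cell cycle genes, 8 of 20 rose, 2 fell and 10 did not pass (camera adjusted p = 0.0216, and adjusted p = 0.524 with an estimated correlation). The adjusted p was 0.0610 without replicate 1 (range 0.000331 to 0.0610). Glycolysis and hypoxia genes divided: 3 of 22 rose, 5 fell and 14 did not pass (camera adjusted p = 0.459). Of the immune regulation genes, 5 of 14 rose, 1 fell and 8 did not pass, with Il18bp (3.22 ± 0.32) higher (camera adjusted p = 0.0983). Of the immediate early and stress genes, 2 of 16 rose, 7 fell and 7 did not pass (2 rose and 9 fell adjusted over the list alone) (camera adjusted p = 0.0983). The same test gave 0.0124 without replicate 3 (range 0.0124 to 0.223). Without replicate 1, Ifit2 was 2.75 and Ifit1 2.53, and 2 MHC class I genes rose, 10 lysosome and protease genes rose and 1 fell, 1 glycolysis and hypoxia gene rose and 4 fell and 1 immediate early and stress gene rose and 2 fell. Without replicate 2, Ifit2 was 0.80 (adjusted p = 0.593) and Ifit1 0.82 (adjusted p = 0.459), and 0 interferon response genes passed (edgeR, 0 rose and 1 fell at an unadjusted p under 0.05), 2 MHC class I genes rose, 3 lysosome and protease genes rose and 1 fell, 1 glycolysis and hypoxia gene rose and 2 fell and 1 immediate early and stress gene rose and 1 fell. Without replicate 3, 10 uptake receptor genes rose and 3 fell, 10 cell cycle genes rose and 1 fell, 3 glycolysis and hypoxia genes rose and 8 fell, 6 immune regulation genes rose and 3 fell and 1 immediate early and stress gene rose and 10 fell. Without a replicate block, 0 interferon response genes passed (edgeR, 0 rose at an unadjusted p under 0.05), 4 MHC class I genes rose, 1 immediate early and stress gene rose and 3 fell. In that fit 1 glycolysis and hypoxia gene rose and 4 fell, and 8 lysosome and protease genes rose and 1 fell.

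Outside the lists, the protease genes Mmp14 (5.36 ± 0.42) and Anpep (5.29 ± 0.47), Cd63 (4.82 ± 0.29) and C1qb (4.67 ± 0.36), which is a marker in the naming lists, rose most in cluster 11, and Bmx (-4.77 ± 0.39), Pi16 (-3.97 ± 0.39), Nfe2 (-3.69 ± 0.24) and Prtn3 (-3.44 ± 0.54) fell most. Itgam was -0.94 ± 0.19 (adjusted p = 6.73e-05) and Ptprc -0.79 ± 0.12 (adjusted p = 4.63e-07). T or NK cell list UMIs were in 9.26% ± 0.274 (unthinned 28.2%) and 0.703% ± 0.246 (unthinned 5.75%) of thinned cluster 11 and classical monocyte-like cells, fibroblast list UMIs in 10.1% ± 2.33 (unthinned 35.6%) and 2.74% ± 1.21 (unthinned 13.8%) and neutrophil list UMIs in 19.2% ± 4.02 (unthinned 63.0%) and 46.6% ± 13.5 (unthinned 91.4%). The B cell list gave 16.4% ± 10.3 (unthinned 45.6%) and 21.6% ± 12.3 (unthinned 66.3%). By replicate, the epithelial list gave 3.30, 7.02 and 1.46% of cluster 11 and 1.29, 1.79 and 0.433% of classical monocyte-like cells, and the melanoma list 0.472, 1.24 and 1.99% and 0.0647, 0.0616 and 0.649%. Of 14513 genes not used to cluster, 5287 changed (edgeR, adjusted p under 0.05), 2641 up and 2646 down. Leave-one-out gave 3313, 3003 and 5442 without replicates 1, 2 and 3. Camera calls kept with an estimated correlation were those for MHC class II, chemokine and M2 panel genes. Without replicate 3, Mmp14 was 6.15, Bmx -6.75, Pi16 -5.55 and Prtn3 -4.43.

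Trem2 cells and cluster 11 had larger shares in replicate 3. The different UMI minimum of the called barcodes is argued against as the whole cause: with the minimum of replicate 3 in every library, the smaller of the 2 ratios of the share in replicate 3 to the higher of the others was 6.29. Library batch cannot be told apart from replicate 3, where the cluster 11 share was 16.0 times the mean of batch 1, since batch 2 holds 1 library. No biological explanation was tested, since the labels put all libraries in 1 group.

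Arg1 and Cxcl9 were both high in cluster 11. For Arg1 in replicate 3, free RNA in equal amounts in every droplet is argued against. There the share of thinned alveolar macrophage-like cells with an Arg1 UMI was 0.0323 times that of cluster 11 cells. Over 3 libraries the highest such ratio was 0.0904, with intervals that overlap in replicates 1 and 2, which cannot be told apart. The unthinned shares given above lay closer together, and Cxcl9 was not covered by this test. Other classes had more Arg1 in replicate 3 than alveolar cells (1.10 CPM), with 17.3 CPM in C1q and 20.4 in Lyve1 cells, so unequal free RNA stays open. A candidate explanation is separate cells in 1 cluster: in replicate 3 cells with both genes numbered 0.0551 times the number if independent, with an upper bound of 0.306, while replicates 1 and 2 had too few cells. Doublets left in the cluster cannot be told apart, since 2 cells over 3 libraries had both genes, and no biological explanation was tested.

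Of the 10 splits of the 6 summed profiles of a comparison, 1 gave as many changed genes, the real one, and 10 splits are too few for a share under 0.05. With only the 2 classes fitted, the real splits gave 8475 (C1q against monocyte-like), 9016 (alveolar against C1q), 6142 (Trem2 against C1q) and 4299 (cluster 11 against cluster 17). The highest of the other splits gave 0 in each comparison (edgeR). For the panels, 1 of 21 draws with class labels permuted within libraries gave as many calls, the real one. It had 485 calls against 22 in the highest other. The classes were made from the same cells, so this is not independent evidence that they differ. Those fits used 1686 genes.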
